A study of Mus musculus with 2 samples.

How the data were processed

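Total RNA of blood cells from fetal liver, sorted into a high and a low population on the ratio of fluorescence at 405 nm to that at 488 nm, was labelled with Cy3 and hybridised in 1 colour, per the labels' protocols. There was 1 array per group, and each array was placed in its group by the sample's source label. Spot intensities (processed, median and background signals) were deposited by the authors as scanner output of Agilent Feature Extraction, which had subtracted background to make the processed signal, per the file headers. The file headers name Feature Extraction 11.0.1.1, whereas the submitters' processing notes name 9.1, and the difference was left unresolved. The value table deposited by the authors holds log2 values whose normalization is not given in the sources used here. Its columns had the same median (4.80) and, once sorted, differed by at most 0.0005, as quantile-normalized columns do, and each column correlated with the log2 signals of its own array at 0.999. The differences between its columns correlated with those of the scanner signals at 0.917, which settled its direction, and it was used as an alternative only.

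Control spots were left out, as were spots marked as non-uniform or population outliers (225 on the SoNar-high and 135 on the SoNar-low array). The log2 of the processed intensity was taken and each array's 75th percentile over 43020 non-control spots subtracted, so values are relative to that percentile. Spots of the same probe were averaged on the log2 scale, giving 39429 probes. A probe counted as measured if most of its spots were well above background by the scanner's flag, and none was saturated, on both arrays, which held for 15975 probes. Each gene was represented by its measured probe with the highest mean signal, and each difference was taken between the arrays within 1 probe. Of 2021 genes with more than 1 measured probe, 175 had probes that differed in sign and by more than 1 (log2), and the median spread between probes of a gene was 0.41. The background signal limits the precision of dim probes.

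Probes were named through the transcript accessions of the array design in a RefSeq gene table of assembly GRCm38.p6, which was used for names only because the array design refers to mm9. Of the probes, 27234 matched 1 gene, none matched several and 12195 stayed unnamed (3389 of them measured) and were not analysed here as genes. The named probes covered 20659 genes, of which 10223 were measured on both arrays.

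With 1 array per group there was no test. Genes were counted as higher or lower by a fixed size of 2-fold. For a gene with no probe well above background on 1 of the arrays, a bound was formed from the bright value and the higher of the dim probe's own value and the lowest value well above background on the dim array, and such genes were counted from 2-fold. The 43 gene lists covered metabolism, erythroid genes, cell types and cell states, with 771 members in the gene table (2 names had no match) and 650 measured members. The median of each list was placed among the medians of 10000 random lists of the same size, drawn from the measured genes in 20 bins of mean signal. A list stood apart if it lay among the highest or lowest 2.5%. Lists with fewer than 3 measured genes received no percentile, which left 42. Some genes are on more than 1 list, such as the succinate dehydrogenase genes under the TCA cycle and complexes II to IV.

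The genes named in the text follow a rule. It took the 12 genes with the largest positive and the 12 with the largest negative difference among genes measured on both arrays, the 5 with the largest bound in each direction among genes measured on 1 array, and in each list the 3 members with the largest absolute difference and the brightest member, of which some are left out for length or are not reported here. Names that are only clone or predicted identifiers were passed over. The groups, the lists, this rule, the size threshold and the other settings listed first below were fixed before the data were examined.

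The settings chosen beforehand were normexp background correction (offset 50), scaling on the median of detected probes, quantile normalization, the deposited value table, no filter on dim probes, a minimum processed signal of 100, the median over a gene's probes, a 3-fold threshold, the list mean and unmatched random lists. The mean spot signal planned for normexp was not used here, and the median spot signal and its local background took its place. Under 50% of spots were well above background on both arrays, so scaling on the 75th percentile of detected probes was added after seeing the data, as was a loess fit of the difference on mean signal (span 0.3). A value counted as moved when it shifted by more than 0.158, the median SD of a log2 difference between spots of 213 probes printed 10 times and measured on both arrays, and a count when it changed by more than 1.5 times.

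The counting rule was tested on simulated differences for the 10223 genes. With spot noise alone, 22 of 50 genes set at 2-fold and all 50 at 3-fold were recovered, and none of 10023 unchanged genes was counted. Every gene was given the same median SD of 0.158, so a count of none was all but fixed beforehand. The 95th percentile of that SD was 0.38, and larger noise of some probes was not simulated. With the observed spread between genes in place of spot noise, 42 of 50 at 3-fold and 47 of 50 at 4-fold were recovered, and 717 of 10023 unchanged genes were counted. That spread was taken from the differences between the 2 arrays, real ones included, so the 717 are not a rate of false calls. Lists of 20 genes shifted by 0.5 stood apart on the high side in 20 of 20 simulations and unshifted lists in 0 of 20. Lists that stood apart on the low side were not counted. With the observed spread a shift of 0.3 stood apart in only 8 of 20, so list differences of that size can be missed. Lists of other sizes were not simulated. The upper limit for standing apart was 0.75 for the 3 embryonic globins and 0.55 for the 6 T and natural killer markers. In such small lists a shift of 0.5 can be missed as well. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.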

Results

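SoNar is a genetically encoded fluorescent sensor of the cytosolic NADH/NAD+ state. Blood cells of mouse fetal liver at stage E13.5 were sorted by the ratio of SoNar fluorescence at 405 nm to that at 488 nm into a SoNar-high and a SoNar-low population, and total RNA of each was hybridised in 1 colour (Cy3) to an Agilent whole-genome array. The comparison asks which genes differ in expression between cells with a high and cells with a low sensor ratio. There were 2 arrays, 1 per group, both from the same slide scan, so the groups share a scan but have no replicates. No p-value is given, differences carry no replicate error, and the number of arrays limits the precision of every value. The strain is labelled C57BL/6 for the SoNar-high sample and C57BL for the SoNar-low sample.

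Of 43020 non-control spots, 21242 (49.4%) were well above background on the SoNar-high array and 18243 (42.4%) on the SoNar-low array. The 75th percentile of the processed signal was 186.5 units on the SoNar-high and 222.2 units on the SoNar-low array, and no spot was saturated. Spots of the same probe, printed 10 times, had a median SD of 0.068 (log2) on the SoNar-high and 0.14 on the SoNar-low array, which gives a median SD of 0.16 for the log2 difference of a single spot pair. That spread covers spot-to-spot error only and not differences between animals, sorts or labelling reactions. All differences are log2 of SoNar-high minus SoNar-low after scaling, so that positive values are higher in SoNar-high cells.

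Among genes measured on both arrays, the 3 largest positive differences belonged to members of the macrophage list, and the 3 largest negative ones to Gzma, Klrd1 and Gzmb. Marco, a scavenger receptor of macrophages, was 12.1-fold higher (processed signal 3424 against 338). The complement chains C1qa and C1qc were 11.6-fold and 9.75-fold higher, and Hmox1, the heme oxygenase that breaks down heme, was 7.15-fold higher. In the other direction, the granule proteases Gzma and Gzmb were 14.9-fold and 6.76-fold lower (Gzma 241 against 4279), and Klrd1, a receptor chain of natural killer cells, was 9.47-fold lower. After normexp background correction all 24 genes with the largest differences had smaller ones, such as C1qa at 4.95-fold, Cdh5 at 3.75-fold, Mirt2 at 3.28-fold, Klrd1 at 4.81-fold and Gzmb at 3.60-fold, and Tmem255a, at 1.74-fold, was under 2-fold. The order among these 24 changed as well, with Mmp9 (7.24-fold) ahead of C1qa and Mcpt8 (3.68-fold) ahead of Gzmb.

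Among 10223 genes measured on both arrays, 540 were at least 2-fold higher and 454 at least 2-fold lower in the SoNar-high array, while 9229 (90.3%) differed by less than 2-fold. The correlation between the arrays across genes was 0.956, where genes are not independent replicates, and the median difference of all genes was -0.08. The split of higher and lower genes depended on the scaling. It was 817 higher and 227 lower when the 75th percentile was taken over detected probes, which moved the median of all genes by 0.18, and 649 higher and 347 lower after a loess fit on mean signal, which moved it by 0.10. With dim probes kept it was 2476 higher and 659 lower. After normexp background correction 251 genes were higher and 257 lower.

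The remaining genes among the 12 with the largest positive difference were Mmp9 (a gelatinase, 3.27), Cdh5 (the endothelial cadherin, 3.07), Vcam1 (an adhesion molecule, 3.03), Asprv1 (3.01), Cd5l (a secreted macrophage protein, 2.93), Scrg1 (2.89), Il18bp (an interleukin-18 inhibitor, 2.82) and Mirt2 (2.80). The remaining genes among the 12 with the largest negative difference were Ccl5 (a chemokine, -2.26), Bach2 (a transcription factor of lymphocytes, -2.24), Mcpt8 (a basophil protease, -2.23), Adgrl4 (-2.16), Tubb2b (-2.09), Spib (an ETS-family transcription factor, -2.05), Tmem255a (-1.99), Xlr4a (-1.97) and Tnfrsf19 (-1.97). A further probe of Tubb2b gave -0.88 and a further probe of Xlr4a gave -0.43, and Xlr4a belongs to a family of closely related copies whose probes can share targets.

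**Figure D1:**
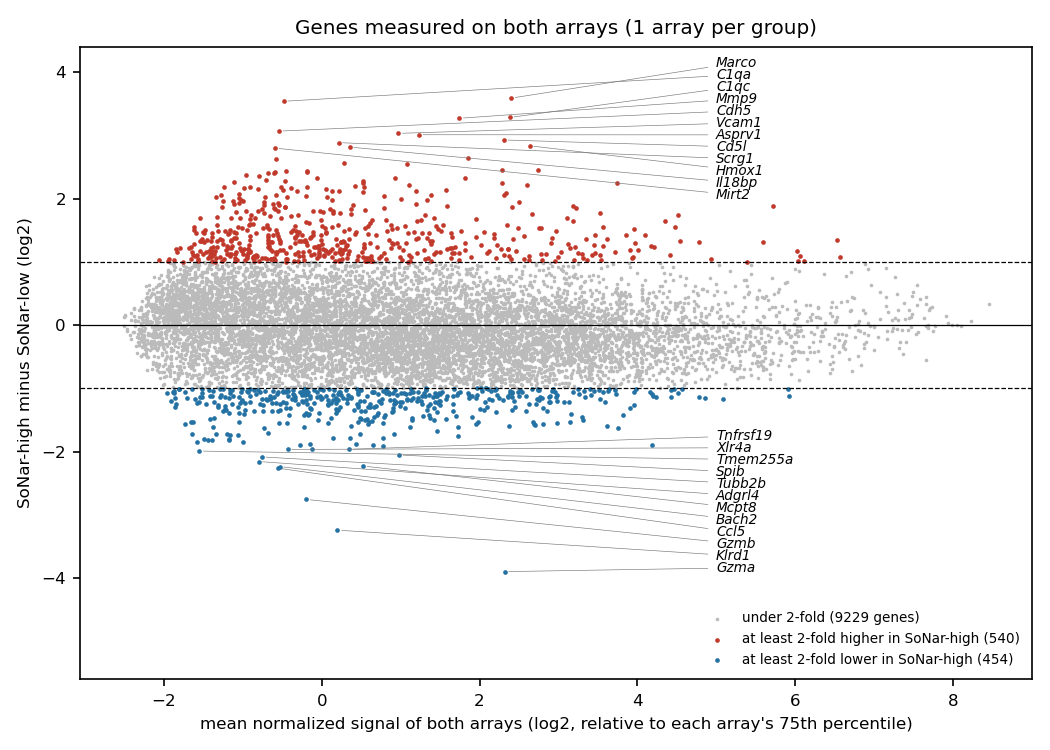
Log2 difference (SoNar-high minus SoNar-low, y axis) against the mean normalized log2 signal of both arrays (x axis) for 10223 genes, each point 1 gene, with dashed lines at 2-fold. The 540 genes at least 2-fold higher are red, the 454 at least 2-fold lower are blue, and the 12 genes with the largest difference in each direction are named.

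A further 202 genes were well above background only on the SoNar-high array with a bound of at least 2-fold, and 34 only on the SoNar-low array. Negative controls varied more on the SoNar-low array (SD 5.82 against 3.64, per the file headers), so dim probes were not detected alike. How far this accounts for the unequal counts was not tested. Fcna (ficolin A) was at least 16.0-fold higher in the SoNar-high array, Timd4, a phosphatidylserine receptor of macrophages, at least 8.07-fold, Irx3 at least 7.52-fold, the receptor kinase Axl at least 6.36-fold and Spp2 at least 6.15-fold. In the SoNar-low array, Il2rb, a chain of the interleukin-2 receptor, was at least 5.74-fold higher, Mex3a at least 5.25-fold, Ifng (interferon gamma) at least 4.61-fold, Ramp3 at least 3.86-fold and the recombinase gene Rag2 at least 3.11-fold. Each of these 10 genes was not well above background on the other array. These bounds were smaller after normexp, a setting that also took the median spot signal in place of the processed signal. The 2 changes were not separated. After normexp the bound of Fcna was 6.10-fold, Timd4 3.43-fold, Irx3 3.22-fold, Axl 2.71-fold and Spp2 2.33-fold. Those of Il2rb (2.37-fold), Mex3a (2.20-fold) and Ifng (2.43-fold) stayed above 2-fold, and those of Ramp3 (1.72-fold) and Rag2 (1.53-fold) were under it. The 202 and 34 genes became 26 and 3 after normexp and 126 and 77 after quantile normalization.

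Erythroid genes were higher as a group in the SoNar-high array. Of 17 measured genes of the red cell membrane and cytoskeleton, 10 were at least 2-fold higher and none at least 2-fold lower, with a median of 1.17 that lay above all 10000 random lists of the same size and mean signal (0.76 after normexp, again above all). Dmtn (dematin) had the largest difference, 2.02, followed by Epb42 (protein 4.2, 1.93) and Ermap (1.76, with its 3 probes between 0.49 and 1.76), while Epb41 (protein 4.1) had 0.46. After normexp Ermap led these with 1.44, followed by Dmtn (1.16) and Epb42 (1.11). Of 11 heme synthesis genes, 4 were at least 2-fold higher and 7 within 2-fold, with a median of 0.94 above all random lists. Among them were Alad (1.58), the ferrochelatase Fech (1.34) and Alas2, the first enzyme of the pathway in erythroid cells (1.24).

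The late erythroblast list had 5 of 16 genes at least 2-fold higher and 11 within 2-fold, with a median of 0.79 above all random lists. Trim10 had 2.07, Tspo2 1.18 and Isg20 1.17, whereas Hemgn had -0.43. Erythroid transcription factors and receptors had a median of 0.48 (percentile 99.9, 1 of 13 genes at least 2-fold higher). Klf1, the erythroid Kruppel-like factor, had 1.31 (0.93 after normexp, under 2-fold), Nfe2 had 0.98 and the erythropoietin receptor gene Epor had 0.95, while Myb, a factor of immature progenitors, had -0.91. Iron uptake and handling genes had a median of 0.38 (percentile 99.7, 1 of 13 at least 2-fold higher; 0.22 after normexp, percentile 98.6), with Slc40a1 (ferroportin, the iron exporter, which macrophages also express) at 2.25, the mitochondrial iron importer Slc25a37 at 0.96 and Fth1 (ferritin heavy chain) at 0.64.

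The measured globin genes were also higher in the SoNar-high array. The 3 measured adult globin genes had a median of 0.37, which did not stand apart from random lists (percentile 95.1), with Hba-a1 at 0.91, Hbb-b2 at 0.37 and Hba-a2 at 0.33. The list lay among the highest 2.5% after normexp (percentile 98.5) and with the mean in place of the median (0.53, percentile 98.6). The 3 embryonic globins, Hbb-y (1.03), Hba-x (0.97) and Hbb-bh1 (0.89), had a median of 0.97 (percentile 99.0). Globin genes are close copies of each other and a probe can bind transcripts of more than 1 of them, so the value of a single globin gene is uncertain.

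Stem and multipotent progenitor markers were lower as a group. Of 18 measured genes, 5 were at least 2-fold lower, 12 were within 2-fold and 1 was at least 2-fold higher, and the median of -0.83 lay below all 10000 random lists. Angpt1 (angiopoietin 1) had -1.90 (-1.26 after normexp) and Mycn -1.25, whereas Ly6a (the Sca-1 antigen) had 1.48, or 0.79 and under 2-fold after normexp. Hoxa9 had -0.11, with a sign that depended on the setting (-0.34 to 0.13). B lymphoid markers had 8 of 12 genes at least 2-fold lower and 4 within 2-fold, with a median of -1.39 below all random lists. Vpreb1, a surrogate light chain gene with a closely related copy, had -1.90, the adaptor Blnk -1.58 and the recombinase gene Rag1 -1.56. Of 6 T and natural killer markers, 2 were at least 2-fold lower (Klrd1 -3.24 and the kinase gene Lck -1.39), with Cd3e at 0.87 and Nkg7 at 0.22. Their median of -0.25 did not stand apart (percentile 24.1), although the mean of -0.64 did (percentile 1.08), as did the median with dim probes kept (-0.91, percentile 0.00). Another 3 listed genes, Il2rb, Gata3 and Cd3g, were well above background only on the SoNar-low array with bounds of at least 2-fold, and Cd3d only on the SoNar-high array. After normexp only the bound of Il2rb stayed at 2-fold.

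Markers of macrophages, hepatic, endothelial and mesenchymal cells were higher as groups. Macrophage and monocyte markers had 9 of 17 genes at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.30 above all random lists. The member at least 2-fold lower was Irf8, a transcription factor of monocyte and dendritic cell progenitors (-1.21), named after its value was seen. Csf1r, the receptor of macrophage colony-stimulating factor, differed by only 0.18, with its 3 probes between -0.09 and 1.02. Hepatoblast and hepatocyte markers had 9 of 14 genes at least 2-fold higher and a median of 1.45, above all random lists. The fibrinogen chains Fgg (2.44) and Fgb (2.04) and the antitrypsin gene Serpina1a (2.09, 1 of several near-identical copies) led the list, and Apoe had 0.71. After normexp Serpina1a (1.94) was ahead of Fgg (1.65) and Fgb (1.31). Endothelial markers had 6 of 11 genes at least 2-fold higher and a median of 1.89, above all random lists, with Stab2 (a scavenger receptor of sinusoids) at 2.64 and Lyve1 at 2.56 (1.94 after normexp) after Cdh5, whereas Egfl7 had -0.31. Mesenchymal and stellate markers had 4 of 6 genes at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.19 above all random lists. Sparc had 2.33 and the collagen gene Col1a1 1.34, whereas the receptor gene Pdgfrb had -1.39 and Vim -0.17, a value that turned positive under other scalings (up to 0.06). With processed signals of at least 100 the mesenchymal list no longer stood apart (percentile 96.4), and after normexp its median was 0.66, with Col1a1 (0.67) and Pdgfrb (-0.86) under 2-fold. These higher non-erythroid lists accompany the higher erythroid lists in the same array.

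Neutrophil and granulocyte progenitor markers had 4 of 17 genes at least 2-fold higher, 13 within 2-fold and a median of 0.44 (percentile 99.99). The collagenase Mmp8 was at 2.46, Lcn2 (lipocalin 2) at 1.89 and Cd177 at 1.66, and S100a9 had 0.44. Megakaryocyte and platelet markers had a median of 0.32 that did not stand apart (percentile 96.7, 1 of 12 at least 2-fold higher and 1 lower; with processed signals of at least 100, percentile 98.5), with Clec1b at 1.86 (1.16 after normexp), Rab27b at -1.20 (its other probe -0.27), Vwf at 0.93 and Pf4 at 0.06. The list of mast cells, basophils and eosinophils had a median of 0.14, which was negative under 3 of 6 other scalings and background corrections (down to -0.12), and a mean of -0.42, and did not stand apart (percentile 83.8). Its 9 genes included Gzmb and Mcpt8, both at least 2-fold lower, beside Epx (eosinophil peroxidase) at 1.46 and Hdc at 0.25, and with processed signals of at least 100 its percentile was 0.94. Of 6 sex-linked markers only Eif2s3y (-0.77) and Ddx3y (-0.61), both on the Y chromosome, were measured on both arrays.

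**Figure D2:**
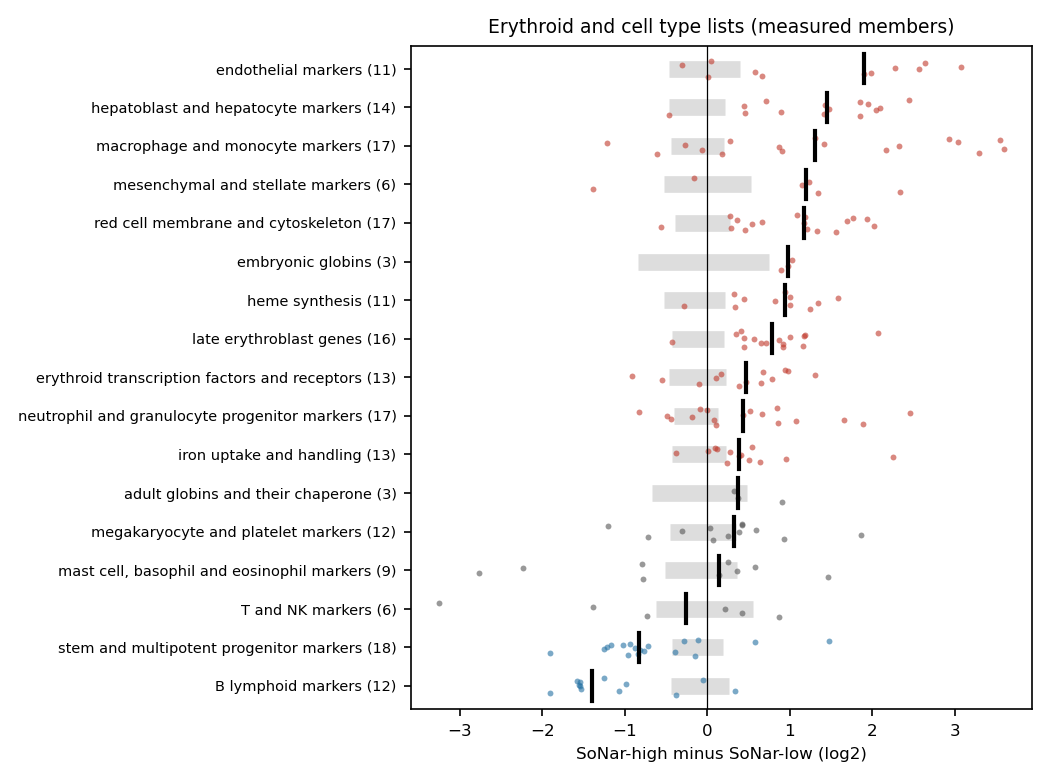
Log2 difference (SoNar-high minus SoNar-low, x axis) of each measured member of the erythroid and cell type lists, with the number of members in brackets, black bars at the list median and grey bars over the central 95% of medians of random lists matched on size and mean signal. Red lists lie above and blue lists below that range; the endothelial median of 1.89 is at the top and the B lymphoid median of -1.39 at the bottom.

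Among metabolic genes, those of glycolysis, the pentose phosphate pathway and antioxidant defence were slightly higher in the SoNar-high array, and ATP synthase genes were lower. Glycolysis genes had a median of 0.14 (percentile 97.8), with 14 genes above 0 and 10 below 0. Of these 24 genes, 1 was at least 2-fold higher, none at least 2-fold lower and 23 within 2-fold. The glucose transporter Slc2a3 had 1.58, the bifunctional enzyme Pfkfb4 0.98 and Pfkl -0.66, and Gapdh had -0.01, a value whose sign depended on the scaling (-0.11 to 0.18). The glycolysis list no longer stood apart after loess (percentile 95.2) or against random lists not matched on signal (percentile 93.7). Pentose phosphate genes had a median of 0.31 (percentile 98.0) and a mean of 0.05. G6pdx, the enzyme of the committed step, had 1.31 and Taldo1 0.31, while the nucleotide precursor synthases Prps2 and Prps1 had -1.42 and -0.85, and 7 of 9 genes were within 2-fold. That list lost its place under 6 of 11 alternatives, down to percentile 77.6 with the mean. Antioxidant defence genes had a median of 0.24 (percentile 99.6), with 1 of 21 at least 2-fold higher. Besides Hmox1 (2.84), Gpx1 (glutathione peroxidase 1) had 0.81 and Gss 0.76. These 3 lists were higher in the same array as the macrophage (1.30), neutrophil (0.44) and red cell membrane (1.17) lists, so a different mix of cells is not separated from a change of metabolism within cells, and Hmox1 was among the 12 genes with the largest positive difference together with macrophage markers.

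None of the 16 ATP synthase genes differed by 2-fold, but 14 had a negative difference, and their median of -0.51 lay at percentile 0.44 (-0.28 after loess, percentile 0.99). Atp5o had -0.90, Atp5l and Atp5pb -0.79 each, and Atp5b -0.26. Complex I genes had a median of -0.31 that did not stand apart (percentile 6.43), with 32 of 37 genes below 0 and 1 at least 2-fold lower. Ndufb2 had -1.32, Ndufv2 -0.98 and Ndufb5 -0.85, while Ndufa13 had -0.04 and was positive under 5 of 6 other scalings. With the mean, -0.35, the complex I list was at percentile 0.39, and against unmatched random lists at 1.79. Complexes II to IV had a median of -0.28 (percentile 12.7; with the mean, percentile 2.21), with 4 of 25 genes at least 2-fold lower. They included Uqcrb (-1.10, with its 3 probes between -1.30 and 0.38), Uqcrfs1 (-1.06) and Cox6b1 (-1.04), and Cox6a1 had -0.18.

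The other metabolic lists did not stand apart from random lists. TCA cycle genes had a median of -0.33 (percentile 12.7), with Ogdh at 1.03 (its 3 probes between 0.16 and 1.03), Fh1 at -0.92, Idh3a at -0.76 and Mdh2 at 0.01. The pyruvate dehydrogenase list had a median of -0.22 (percentile 22.3), with Pdhx at -1.14 and Dld at -1.01 (its other probe -0.60). Serine and one-carbon genes had -0.35 (percentile 8.08), with Mthfd2l at -0.91 and Psph at -0.83 beside Shmt1 at 0.94, whose 2 probes ranged from -0.15 to 0.94. Genes of NAD synthesis and consumption had -0.22 (percentile 28.7), with the NAD-consuming enzyme Cd38 at 1.73 and the deacylases Sirt5 and Sirt3 at -0.94 and -0.88. A further 4 lists had medians close to 0, whose sign changed under at least 1 other scaling (for NADH shuttles only where a constant was added to every gene). They were NADH shuttles (-0.12, percentile 52.6, Mdh1 -0.86), fatty acid oxidation (-0.10, percentile 48.3, Decr1 -0.87), cholesterol synthesis (-0.11, percentile 44.9, Cyp51 -1.32) and hypoxia targets (-0.14, percentile 34.6, Ndrg1 0.68). Mitophagy and autophagy genes had a median of 0.01 (percentile 83.2), with Map1lc3a at 1.16.

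Genes of cell division did not stand apart. The S phase list had a median of -0.20 (percentile 31.2), with 1 of 24 genes at least 2-fold lower, and its median was 0.00 after loess. Slbp had -1.18 (its other probe 0.03), Cdc6 -0.91 (its other probe 0.14), Mcm3 -0.86 and Mcm6 -0.11, whose sign depended on the setting (-0.19 to 0.06). The G2 and mitosis list had -0.20 (percentile 38.3), with none of 21 genes at 2-fold, Bub1 at -0.95 and Cdk1 at -0.83. Cell cycle inhibitors had 0.08 (percentile 81.5), with Cdkn1c at 0.96.

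Among the lists of translation and stress, only the interferon response stood apart under the scaling used throughout, with a median of -0.59 (percentile 1.63) and 1 of 8 genes at least 2-fold lower. Ifi27l2a had -1.36, Ifitm3 -0.82 and Isg15 -0.74. That list did not stand apart after normexp (percentile 8.15) or with dim probes kept (0.03, percentile 15.1), and it lay just inside the central range with processed signals of at least 100. Cytosolic ribosomal proteins had -0.16 (percentile 44.4, all 39 within 2-fold, Rps4x -0.97), a median that turned positive only where a constant was added to every gene, and the list lay at percentile 2.22 in the deposited value table. Mitochondrial ribosomal proteins had -0.22 (percentile 29.3, 2 of 29 at least 2-fold lower, Mrpl16 -1.30). Ribosome biogenesis and Myc targets had -0.27 (percentile 20.1, 3 of 20 at least 2-fold lower), with Nop58 at -1.41 and the nucleolar gene Npm1 at -1.12, whose 5 probes ranged from -1.12 to 0.01. The p53 target list had -0.39 (percentile 8.68), with Phlda3 at 1.84 and Sesn1 at -1.39. Unfolded protein and amino acid stress genes had 0.16 (percentile 95.8; after loess, 97.6), with Chac1 at 0.75 and Atf4 at -0.73. Immediate early genes had -0.07 (percentile 67.6), with Egr1 at -0.91, and their median was positive under 5 of 6 other scalings.

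**Figure D3:**
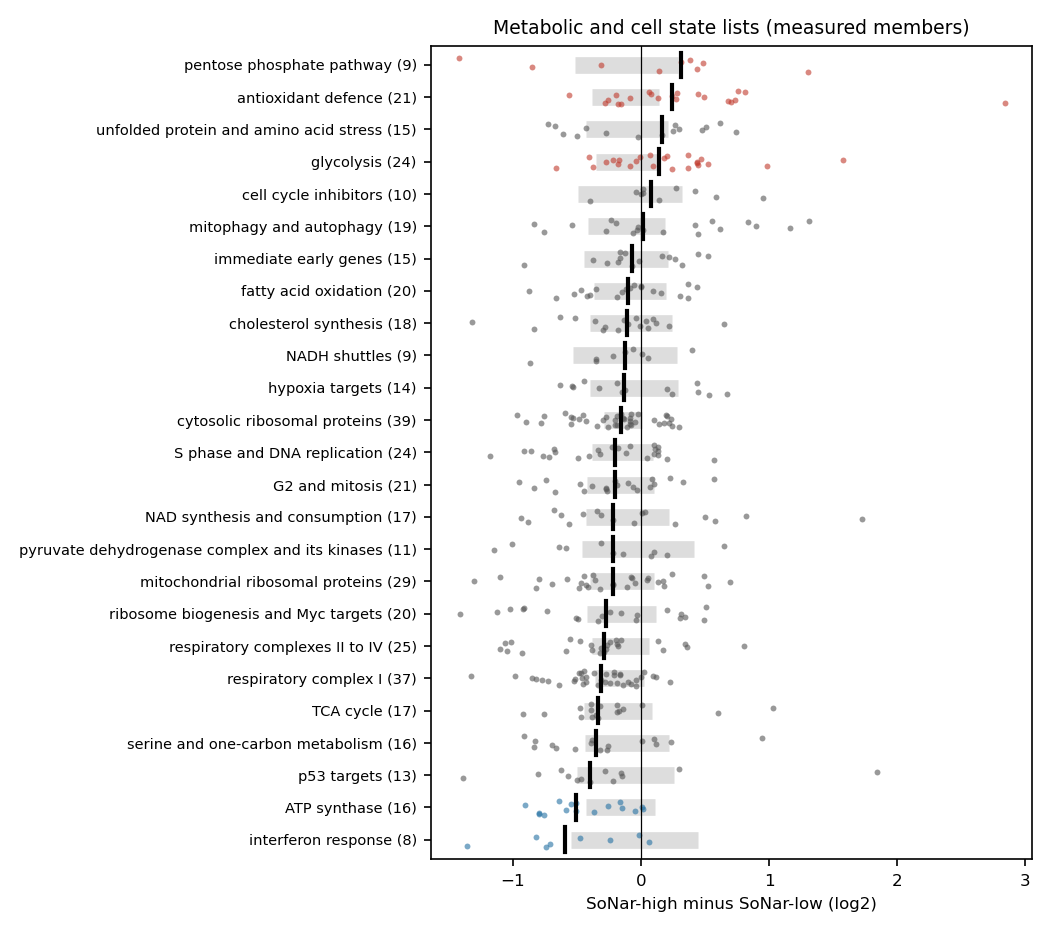
Log2 difference (SoNar-high minus SoNar-low, x axis) of each measured member of the metabolic and cell state lists, drawn as for the cell type lists, with black bars at medians and grey bars over the central 95% of random medians. Pentose phosphate (median 0.31), antioxidant (0.24) and glycolysis (0.14) genes lie above that range, and ATP synthase (-0.51) and interferon response (-0.59) genes below it.

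Across all families, 14 of 42 lists lay among the highest 2.5% of their random lists and 4 among the lowest 2.5%. Lists of unrelated genes would give 1.05 on each side on average. Genes of 1 list can vary together between any 2 samples, so that number is no measure of chance for these lists. The medians of these 18 lists kept their sign under each of the 6 other scalings and background corrections tried. All 6 moved the median of all genes upward, by 0.03 to 0.18, so the 14 high lists could hardly have changed sign. With dim probes kept, a setting outside these 6, the interferon median turned to 0.03. Of 56 named list members at least 2-fold apart and not among the 24 genes with the largest differences, 17 were under 2-fold after normexp, among them Prps2, Pdhx, Ogdh, Cox6b1, Cyp51, Map1lc3a, Hbb-y, Mycn, Rab27b and Epx. These percentiles describe the 2 arrays and are not a test between the populations.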

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

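Scaling on the 75th percentile of detected probes and the loess fit were chosen after seeing the data; the other settings were planned. Of the 18 lists that stood apart, 14 did so under every alternative that gave them a value (10 for embryonic globins, 11 for the others, of which 2 add a constant and cannot change a percentile), and the exceptions were glycolysis, pentose phosphate, mesenchymal and interferon genes. Of the 24 other lists, 16 never stood apart and 8 did under at least 1 alternative. All 540 higher and 373 of 454 lower genes were kept with scaling on the median of detected probes (623 and 373 in all, with no list moved), against 249 and 211 after normexp, when 17 of the 56 other named genes at least 2-fold apart were under 2-fold. Background limits dim probes, and the offset of normexp draws their differences towards 0. The normexp setting also took the median spot signal in place of the processed signal, and the 2 were not separated.

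Counts of higher and lower genes were 251 and 257 after normexp, 817 and 227 with scaling on the 75th percentile of detected probes, and 146 and 48 at 3-fold. Higher genes numbered 2476 with dim probes kept, when 20655 genes were counted, and 329 with signals of at least 100, when 7800 were. Genes well above background on the SoNar-high or SoNar-low array only numbered 26 and 3 after normexp, 126 and 77 after quantile normalization, and 126 and 79 in the deposited table. The adult globin median was 0.567 after quantile normalization, 0.580 in the deposited table, 0.546 with the 75th percentile of detected probes, 0.597 after loess and 0.534 as a mean. The S phase median was -0.041, -0.033, -0.023 and 0.000 under the first 4 of these. Scaling on the 75th percentile of detected probes adds 0.178 to every gene, which gave glycolysis 0.316, complex I -0.135 and stem markers -0.651. After loess complex I was at -0.136 and stem markers at -0.655, and the stem mean was -0.630. The interferon median turned to 0.026 with dim probes kept. Except for the constant shift and the stricter or looser filters and thresholds, the cause was not tested.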

Other observations

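The families of genes sharing a symbol, and all tests below except that of dim B lymphoid probes, were chosen after the results were seen. Of 26 families examined, 4 lay among the highest and 4 among the lowest 2.5% of matched random lists; having been chosen after these data were seen, these counts are not set against chance. All 11 measured snRNP protein genes were below 0, with a median of -0.69 (percentile 0.12), led by Snrpb2 (-1.56), Snrpa1 (-1.21) and Snrpe (-1.06), whereas SR splicing factors did not stand apart (median -0.37, percentile 15.8). The 205 measured zinc finger genes named Zfp had a median of -0.21 (percentile 0.01), with 143 below 0, and 5 of 6 Gimap genes, GTPases of lymphocytes, were below 0 (median -0.79, percentile 0.26), led by Gimap8 (-1.23) against Gimap4 at 0.96. The 29 ubiquitin-conjugating enzymes had a median of -0.38 (percentile 2.21), near the edge of that range. These 4 low families kept their sign under 6 other scalings and background corrections.

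Higher families were those of Fc receptors, with 4 of 5 at least 2-fold higher (median 1.65, above all 10000 random lists; Fcgr4 2.20, Fcer1g 1.65), and of Serpina protease inhibitors, with 5 of 8 at least 2-fold higher (median 1.68, above all random lists), 4 of them near-identical Serpina1 copies. The 5 measured apolipoprotein genes were all above 0 (median 0.99, percentile 99.9), and collagens had a median of 0.56 (percentile 98.0). Clec4f, a lectin of liver macrophages, was at least 5.79-fold higher in the SoNar-high array, the plasma protein gene Gc at least 4.85-fold, and Pklr, the pyruvate kinase of red cells and liver, at least 3.76-fold (2.60-fold, 2.37-fold and 1.98-fold after normexp), none being well above background on the SoNar-low array. In the B lymphoid list, Dntt was the exception at 0.34, with processed signals of 59.9 and 56.6, and Pax5 had -0.05. Xist was not well above background with either of its 2 probes on either array. Of the Y-linked genes, Eif2s3y and Ddx3y were measured on both arrays, while Uty and Kdm5d were well above background on neither.

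Macrophage, hepatic and endothelial markers were higher in the SoNar-high array. A smaller erythroid share with unchanged expression per cell would lower erythroid genes and raise all other types alike. The red cell membrane list instead lay 1.25 above the median of all genes, with its lower quartile above that median. The stem (-0.83) and B lymphoid (-1.39) medians were lower, not raised. The erythroid lists were known to be high before this was set up. Higher expression per erythroid cell could hide a smaller share, so a smaller share otherwise stays open. Normexp, quantile normalization, the deposited table and loess moved genes unequally and left the 3 lists at a lowest percentile of 100 and a lowest median of 1.15. The pattern was thus not removed by these settings. They moved the median of all genes by only 0.03 to 0.10, so lists picked for such high medians could hardly have lost their place. The columns of the deposited table matched as quantile-normalized ones do, so it is no separate check from quantile normalization. Background correction and normalization in general are not excluded. Scalings that add a constant cannot move a percentile and tested nothing. A larger share of these cells stays open: 88.1% of the members lay above the median of all genes, but that restates the pattern and decides nothing, and Irf8 (-1.21), Ccr2 (-0.61), Ctss (-0.26) and Cx3cr1 (-0.07, its other probe 1.00) of the macrophage list, Krt18 (-0.47) of the hepatic and Egfl7 (-0.31) of the endothelial list lay below 0, all but Egfl7 named after their values were seen. A change of expression within cells and a difference between the sorted populations stay open too, and 1 array per group cannot separate either from a difference between samples.

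ATP synthase genes were lower in the SoNar-high array, while complexes I to IV did not stand apart; both were first set up as 1 group of lists and split after the result was seen. Random lists matched on signal share any trend of the difference with mean signal. The ATP synthase list lay at percentile 0.44 among them, and at 0.99 after loess, which moved its median from -0.51 to -0.28. It was thus lower than genes of like signal on these 2 arrays. The list was split off after that percentile was seen, and loess removes much the same trend as the matching. These values are therefore no independent test of such a trend. For complexes I to IV the higher of the 2 percentiles after loess was 10.52, which decides nothing. A shift shared with other housekeeping genes stays open for both: the medians lay at -0.32 (ATP synthase, 95% bootstrap interval over genes -0.50 to 0.03) and -0.11 (complexes I to IV, -0.27 to 0.02) relative to 68 ribosomal protein genes. Those genes pool the cytosolic and mitochondrial lists, and some mitochondrial ones were dim. The intervals cover the spread between genes and not between samples. A different mix of cells also stays open and was not tested for these genes: in the same array the macrophage (1.30), endothelial (1.89) and red cell membrane (1.17) medians were higher and the stem (-0.83) and B lymphoid (-1.39) medians lower.

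B lymphoid markers were lower in the SoNar-high array. Noise of dim probes is argued against by the 9 members with signals of at least 100 on both arrays, whose median lay at -1.41 relative to all such genes. Not every other cell type was lower alike: macrophage (1.30), hepatic (1.45), endothelial (1.89), mesenchymal (1.19) and neutrophil (0.44) medians were higher. Dilution by such cells stays open, since a comparison with the other cell type lists could not decide it. The lowest median among the other 9 cell type lists, that of stem and progenitor markers, was only 0.56 above the B lymphoid median. It was level with the B lymphoid upper quartile (-0.83), although T and natural killer (-0.25) and megakaryocyte (0.32) medians lay higher. A smaller share of B lymphoid cells and lower expression per cell stay open as well, since the 83.3% of members below the median of all genes restate the pattern and decide nothing.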
